A study of Homo sapiens with 6 samples.

How the data were processed

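RNA was extracted with a silica column kit and libraries were made by a commercial provider, per the labels' protocols, from MDA-MB-231 cells with a control hairpin (3 samples) or hairpin RNA against RNF20 (3 samples). The labels do not say how many hairpins against RNF20 were used or whether the cells were pools or clones. Per the submitters' processing notes, quality was checked with FastQC 0.12.1 and reads were aligned to hg38 with STAR 2.7.11a. The annotation release, any trimming and how the libraries were enriched for mRNA are not given in the sources used here. The authors deposited, for each library, a table of raw read counts per gene with 62703 versioned Ensembl genes and columns of counts without strand and for each strand. The strand columns were close to equal in every library (50.1% to 50.2% in 1 of them), so the counts without strand were used. In these counts reads over exons of more than 1 gene are recorded as ambiguous, whatever their strand (10.7% to 11.2% of all reads). Genes that overlap others, antisense genes included, are therefore underestimated, and their fold changes rest on the parts they do not share. Lines that name no gene (unmapped, multimapping, outside annotated exons, ambiguous) held 20.9% to 24.1% of all reads recorded and were left out of library sizes and tests. Reads mapping to several places are not in the gene counts, so near-identical genes and pseudogenes are underestimated.

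Gene counts totalled 21988826 to 29685306 per library. A symbol was matched by identifier for 62686 of the genes. Positions, gene types, lengths and GC content came from GENCODE 29 on the same assembly, which holds 58264 of the genes and may not be the release the authors used.

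Counts were analysed with R 4.3.3 and edgeR 4.0.16: genes were kept by filterByExpr (minimum count 10), scaled by TMM and tested with the quasi-likelihood F-test with robust estimation, shRNF20 against shControl, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes are the fold change divided by the root of the F statistic. CPM values use TMM library sizes, and means are given with SD over 3 libraries. No label says that replicates are separate cultures, so p-values measure only the spread between these samples, which may be technical. Shares of reads were compared by an exact two-sided permutation test.

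The test, the gene lists (7 on the question of the title, 11 on other biology, 5 on library quality and other cell types), the rule for named genes and the alternatives listed first below were fixed before the data were examined. Named genes are RNF20, RNF40, KDM1A, CDK9 and CD274; the 6 genes with the largest rise and the 6 with the largest fall among genes past the threshold with a mean log2-CPM of at least 3, groups that do not overlap and a symbol that is not a clone name; and the 2 members with the smallest p of each of the first 18 lists. The values of 1 gene that this rule names are not reported here. For the other lists the most changed member is named. Members named because 5 or fewer of a list moved 1 way, and genes named in the closing section, were chosen after their values were seen. Lists were tested with camera (limma 3.58.1) on log2-CPM (prior count 2) at a preset correlation of 0.01, two-sided and adjusted over the 23 lists, and again with an estimated correlation and with fry, which asks whether members move 1 way on balance and not whether they differ from other genes.

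Alternatives were RLE and upper quartile scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, a stricter filter (CPM of at least 1 in 3 libraries), replicate number as a block, the sum of the strand columns, a minimum of 2-fold, a test against 1.2-fold, and each library left out in turn. Added after seeing the data were a fit with the 3 shRNF20 libraries summed to 1 sample and a fit without mitochondrial genes. Counts were also simulated from the real means and library sizes for the comparison of shRNF20 with shControl. Far fewer genes were changed than were called in the data, and both groups were given the same spread, unlike the real libraries. The simulation therefore does not give the recovery or false call rate of the real comparison. In that step of 15414 genes, 27 of 67 genes changed 1.5-fold, 44 of 67 changed 2-fold and 62 of 66 changed 4-fold were recovered, all in the right direction, and 10.1% of the calls were unchanged genes, above the 5% nominal rate.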

Results

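Messenger RNA was measured by bulk RNA sequencing in MDA-MB-231, a human triple-negative breast cancer cell line, carrying either a control short hairpin RNA (shControl, 3 libraries) or hairpin RNA against RNF20 (shRNF20, 3 libraries). RNF20 is an E3 ubiquitin ligase that, with its partner RNF40, attaches ubiquitin to histone H2B in transcribed genes. Counts assigned to genes totalled 29685306, 25269535 and 23786533 in the shControl libraries and 26000971, 21988826 and 28265573 in the shRNF20 libraries. The series title ties RNF20 to immunosuppression, the kinase CDK9 and the histone demethylase LSD1, so the comparison asked how loss of RNF20 altered immune genes and the genes of that machinery.

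RNF20 mRNA was lower in each of the 3 shRNF20 libraries, at 12.5 ± 1.52 CPM (counts per 1e6 counts; SD, n = 3) against 58.1 ± 0.34 CPM in the shControl libraries. The knockdown left the cells with 4.66-fold less RNF20 mRNA (ENSG00000155827.12, GRCh38 chromosome 9, 101533851 to 101563344; log2 fold change -2.22, SE 0.11, edgeR adjusted p = 5.23e-06). In the separate libraries RNF20 stood at 57.8, 58.5 and 58.0 CPM in shControl and at 14.1, 12.2 and 11.1 CPM in shRNF20. The rest of the transcriptome differed widely between the groups. Of 15797 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 4528 rose and 4704 fell, which is 58.4% of the genes tested. At least a 2-fold change was found for 1655 of the genes that rose and 1856 of those that fell.

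Among genes with a mean log2-CPM of at least 3, the largest fall was that of MUC5AC, a secreted gel-forming mucin (chromosome 11, 1157953 to 1201138), which went from 1585 ± 676 CPM to 25.4 ± 1.80 CPM (log2 fold change -5.96, SE 0.34, edgeR adjusted p = 9.30e-06). It was followed by the neutrophil chemokine CXCL5 (-4.76), the desmosomal protein DSP (-4.62), the elastase inhibitor PI3 (-4.58), the metalloprotease ADAMTS9 (-4.32) and the cystatin CST1 (-4.25). The shControl libraries varied widely for DSP (57.5 ± 53.2 CPM), PI3 (19.6 ± 16.6 CPM), ADAMTS9 (28.1 ± 24.0 CPM) and CST1 (50.4 ± 46.2 CPM). For these genes no shRNF20 library reached the lowest control. The log2 fold change of PI3 ranged from -5.03 to -3.65 over the alternatives listed above. Without shControl replicate 1 the log2 fold changes of DSP, ADAMTS9 and CST1 were -3.59, -3.47 and -3.27, and these 3 genes no longer passed with the shRNF20 libraries summed to 1 sample. The largest rise under the same limit was that of NNAT, an imprinted gene encoding the membrane proteolipid neuronatin (chromosome 20, 37521206 to 37523693), which went from 1.26 ± 0.38 to 16.6 ± 1.68 CPM (log2 fold change 3.72, SE 0.22, edgeR adjusted p = 9.30e-06). The other large rises were MT-ND1 (3.34), MT-ND6 (2.87) and MT-ND5 (2.81), which encode subunits of respiratory complex I on the mitochondrial genome, and the nuclear pseudogenes MTATP6P1 (2.82) and MTCO1P12 (2.74). These pseudogenes are near copies of mitochondrial sequence, so their counts are uncertain.

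**Figure D1:**
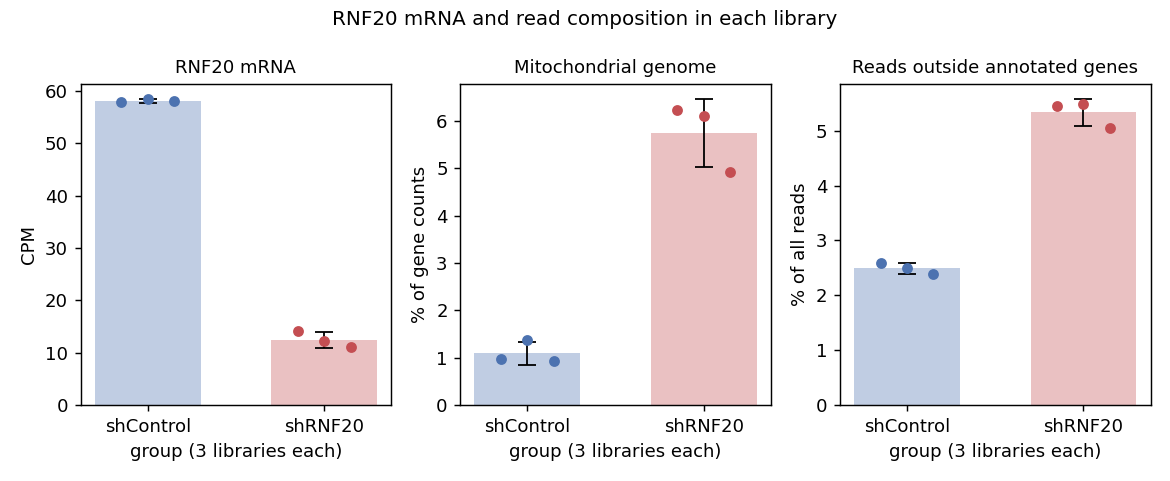
Each point is 1 library, bars are means of 3 libraries and error bars are SD. The panels show RNF20 mRNA in CPM, the percent of gene counts from the mitochondrial genome and the percent of all reads outside annotated exons. The last panel is headed as reads outside annotated genes, but intronic reads are included in it. RNF20 mRNA is lower and both read shares are higher in every shRNF20 library than in any shControl library.

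Cytokine and chemokine genes had the lowest median of the 23 gene lists. Of 22 tested, 18 fell and 1 (CXCL16, 0.71) rose, with a median log2 fold change of -2.06. CXCL5 dropped from 49.7 ± 14.2 to 1.83 ± 0.16 CPM (SE of the log2 fold change 0.23, edgeR adjusted p = 5.47e-06), and the myeloid growth factor CSF2 from 99.7 ± 18.1 to 18.6 ± 0.33 CPM (log2 fold change -2.43, SE 0.13, edgeR adjusted p = 7.94e-06). Interferon-stimulated genes were also mostly lower: 30 of 44 fell and 8 rose, with a median of -0.75. ISG15, a ubiquitin-like protein induced by interferon, fell from 337 ± 41.2 to 99.7 ± 2.19 CPM (-1.76, SE 0.10), and IFI44 from 34.4 ± 1.21 to 11.5 ± 0.14 CPM (-1.58, SE 0.09). Among NF-kB targets 12 of 22 fell, with a median of -0.40; TNIP1, an inhibitor of NF-kB signalling that is itself induced by it, went from 521 ± 30.1 to 94.5 ± 0.59 CPM (-2.46, SE 0.07), and TNFAIP2 also fell (-1.36, SE 0.11). NFKBIZ (0.71) and BIRC2 (0.63) rose. The edgeR adjusted p-values of ISG15, IFI44, TNIP1 and TNFAIP2 were 8.37e-06, 9.30e-06, 2.97e-06 and 3.15e-05.

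Tested as groups with camera at a preset correlation, the cytokine and chemokine genes gave an adjusted p of 1.94e-05, the interferon-stimulated genes 5.26e-04 and the NF-kB targets 0.00454. None of these passed when the correlation between members was estimated (adjusted p = 0.256 for cytokines and chemokines, adjusted p = 0.365 for interferon-stimulated genes and adjusted p = 0.256 for NF-kB targets with an estimated correlation). The estimate for NF-kB targets was -0.0029, below the preset 0.01, so correlation among members does not account for the loss of that call. Among sensors of foreign nucleic acid and their signalling partners, 9 of 20 fell, including the RNA sensor IFIH1 (-1.57, SE 0.18, edgeR adjusted p = 1.54e-04) and the ubiquitin ligase TRIM25 (-0.61, SE 0.07, edgeR adjusted p = 1.61e-04). MYD88 (0.58) and TBK1 (0.43) rose. The median of this group was -0.30 and it did not pass as a group (camera adjusted p = 0.314).

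**Figure D2:**
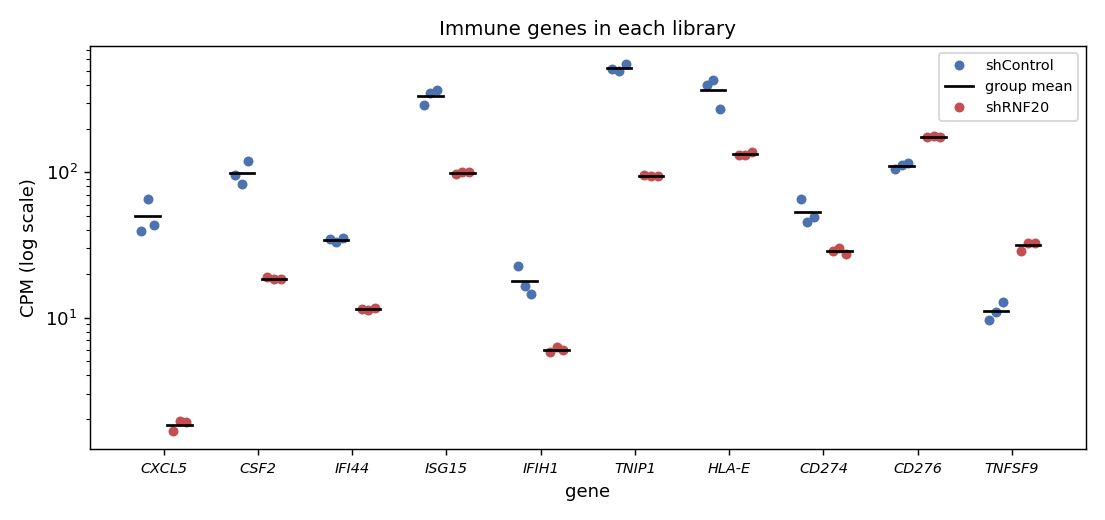
Each point is 1 library (3 per group) and each line a group mean, in CPM on a log axis, for 10 immune genes. CXCL5, CSF2, IFI44, ISG15, IFIH1, TNIP1, HLA-E and CD274 are lower in all 3 shRNF20 libraries than in any shControl library, and CD276 and TNFSF9 are higher.

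The ligands of immune checkpoints moved in both directions. CD274, which encodes the checkpoint ligand PD-L1, fell from 53.3 ± 10.4 to 28.8 ± 1.32 CPM (log2 fold change -0.89, SE 0.14, edgeR adjusted p = 6.75e-04), and VTCN1 (-2.38), CD24 (-1.57) and LGALS9 (-1.75) fell as well. CD276, a B7 family ligand, rose from 111 ± 5.74 to 176 ± 1.44 CPM (0.66, SE 0.07, edgeR adjusted p = 8.69e-05), and the costimulatory ligand TNFSF9 from 11.1 ± 1.58 to 31.4 ± 2.28 CPM (1.51, SE 0.13, edgeR adjusted p = 3.98e-05); TNFRSF14 (0.65), NECTIN2 (0.26) and PVR (0.20) rose too. Of 13 ligands tested, 5 rose and 4 fell. Without shRNF20 replicates 1, 2 and 3 in turn, 3, 2 and 2 of 15 rose and 5 fell each time. With a shControl library left out, 4 or 5 rose and 4 to 6 fell. The group of 13 gave a camera adjusted p of 0.887. Its median (-0.05) and mean (-0.26) were below 0 while the direction of the test was upward, and the median turned positive without shControl replicate 1 (0.05). In the machinery that loads and displays peptides on MHC class I, 7 of 21 genes fell. The nonclassical class I molecule HLA-E went from 369 ± 86.1 to 134 ± 3.72 CPM (-1.46, SE 0.16, edgeR adjusted p = 1.11e-04) and the chaperone CALR from 1006 ± 48.3 to 681 ± 22.4 CPM (-0.56, SE 0.07, edgeR adjusted p = 2.19e-04). ERAP2 (0.71) and TAPBPL (0.58) rose. The group median was -0.13 (camera adjusted p = 0.294); without shControl replicate 3 the group passed (median -0.25).

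KDM1A, which encodes LSD1, did not pass the test. Its mRNA was at 156 ± 7.46 CPM in shControl and 149 ± 3.03 CPM in shRNF20 (log2 fold change -0.07, SE 0.07, edgeR adjusted p = 0.397). Members of the LSD1-CoREST complex were more often lower: of 13 tested, KDM1A included, 7 fell, among them HMG20B (-0.82, SE 0.08, edgeR adjusted p = 6.31e-05) and GSE1 (-0.98, SE 0.16, edgeR adjusted p = 8.61e-04), while RCOR3 (0.51) and ZMYM2 (0.37) rose. The complex had a median of -0.40 and did not pass as a group (camera adjusted p = 0.257).

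CDK9, the kinase of the elongation factor P-TEFb, fell from 67.3 ± 3.56 to 50.9 ± 1.43 CPM (log2 fold change -0.40, SE 0.07, edgeR adjusted p = 0.00184). RNF40 rose slightly, from 93.3 ± 9.96 to 118 ± 0.86 CPM (0.34, SE 0.09, edgeR adjusted p = 0.00901). Of 27 factors of H2B ubiquitination and elongation, 13 rose and 3 fell (CDK9, CDK12 at -0.46 and HEXIM1 at -0.25). SUPT5H, a subunit of the elongation factor DSIF, rose from 239 ± 2.23 to 384 ± 15.5 CPM (0.69, SE 0.06, edgeR adjusted p = 5.77e-05), and WAC, an adaptor that brings RNF20 and RNF40 to RNA polymerase II, rose from 191 ± 3.69 to 297 ± 2.64 CPM (0.64, SE 0.06, edgeR adjusted p = 6.60e-05). The group median was 0.21, with a camera adjusted p of 0.0454 and an adjusted p = 0.687 with an estimated correlation. The CDK9 and RNF40 differences no longer passed when the 3 shRNF20 libraries were summed to 1 sample (log2 fold changes -0.38 and 0.36), and the group call was lost without any 1 of shControl replicates 1 and 2 or shRNF20 replicates 1, 2 and 3 (medians 0.19, 0.22, 0.17, 0.21 and 0.20).

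Genes of mitosis were more often lower and histone genes more often higher. Of 27 genes of G2/M and mitosis 17 fell and 10 did not pass, with a median of -0.61. As a group they gave a camera adjusted p of 1.03e-04, and an adjusted p = 0.766 with an estimated correlation. Without shControl replicate 2, 24 fell (median -0.74). Without any other 1 library 15 or 16 fell, and 2 rose without shControl replicate 1 (median -0.53). The kinetochore motor CENPE fell from 110 ± 19.8 to 39.5 ± 1.90 CPM (-1.48, SE 0.13, edgeR adjusted p = 3.96e-05) and the cytokinesis motor KIF20A from 149 ± 14.1 to 73.5 ± 0.73 CPM (-1.02, SE 0.08, edgeR adjusted p = 3.16e-05). For G1/S and DNA replication, 14 of 31 genes fell, including the transcription factor E2F1 (-2.14, SE 0.16, edgeR adjusted p = 2.28e-05) and the replication kinase CDC7 (-0.89, SE 0.11, edgeR adjusted p = 2.39e-04). CCNE2 (0.65), CDC6 (0.55), GINS2 (0.52) and GINS1 (0.28) rose, but no member of the list passed as higher when any 1 shRNF20 library was left out. With 1 library left out, 10 to 21 members fell. The group did not pass (median -0.34, camera adjusted p = 0.133). It passed with DESeq2 (-0.35), without a filter on low counts (-0.38) and without shControl replicate 2 (-0.49). Of 16 replication-dependent histone genes 10 rose and 6 did not pass, with a median of 0.75 (camera adjusted p = 0.0309, and adjusted p = 0.766 with an estimated correlation). The group call was also lost without a filter on low counts (median 0.59), with the shRNF20 libraries summed to 1 sample (0.77) and without shRNF20 replicate 3 (0.65). H2BC21 rose from 4.23 ± 0.74 to 11.7 ± 0.67 CPM (1.47, SE 0.16, edgeR adjusted p = 1.37e-04) and H2BC6 from 0.84 ± 0.24 to 3.27 ± 0.17 CPM (1.95, SE 0.27, edgeR adjusted p = 3.87e-04). Both counts are low, and histone genes of 1 family share sequence.

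Genes of the MAPK and AP-1 response were more often lower than higher. Of 27 tested, 12 fell, 14 did not pass and 1 (IER2, 0.46) rose, with a median of -0.43 (camera adjusted p = 0.00682, and adjusted p = 0.766 with an estimated correlation). The ETS factor ETV4 went from 54.3 ± 3.13 to 20.8 ± 0.65 CPM (-1.38, SE 0.09, edgeR adjusted p = 1.13e-05) and MYC from 164 ± 5.75 to 92.6 ± 3.79 CPM (-0.82, SE 0.07, edgeR adjusted p = 3.55e-05). MDA-MB-231 cells carry mutant p53. Among p53 targets 6 of 20 rose and 6 fell, including the death receptor FAS (-1.44, SE 0.14, edgeR adjusted p = 7.50e-05) and the stress cytokine GDF15, which went from 438 ± 178 to 56.7 ± 2.72 CPM (-2.95, SE 0.29, edgeR adjusted p = 7.78e-05). The p53 group gave a median of 0.01, a mean of -0.24 and a camera adjusted p of 0.858, with the test in the direction of the mean. The median was negative without any 1 library but shControl replicate 2 (0.02). Rises numbered 6, 5 and 2 without shControl replicates 1, 2 and 3. They numbered 2, 3 and 2 without shRNF20 replicates 1, 2 and 3.

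Cholesterol genes were more often higher. Of 23 genes of cholesterol synthesis and uptake 11 rose and 2 fell (PMVK at -1.51 and MVD at -0.40), with a median of 0.30 (camera adjusted p = 0.0189, and adjusted p = 0.291 with an estimated correlation). HMGCS1, an early enzyme of the pathway, rose from 20.01 ± 0.89 to 64.9 ± 4.11 CPM (1.70, SE 0.09, edgeR adjusted p = 6.58e-06). In the unfolded protein and integrated stress response 11 of 27 genes fell. Its 5 rises were SLC7A11 (1.08, SE 0.10, edgeR adjusted p = 4.48e-05) and SLC3A2 (1.26, SE 0.10, edgeR adjusted p = 2.43e-05), which form the cystine transporter, DNAJB9 (0.65), CRELD2 (0.61) and SESN2 (0.49). Among hypoxia and glycolysis genes 10 of 27 fell, including VEGFA (-1.12, SE 0.08, edgeR adjusted p = 1.73e-05) and the hexokinase HK2 (-0.88, SE 0.07, edgeR adjusted p = 2.27e-05), and 5 rose (ALDOA at 1.67, ADM at 1.18, SLC2A3 at 0.99, PFKFB4 at 0.50 and KDM3A at 0.31). The stress and hypoxia groups did not pass (medians -0.17 and -0.11, camera adjusted p = 0.449 and 0.296). The stress median moved to -0.33 without shControl replicate 1, with 16 of 27 lower, and to -0.07 without shControl replicate 3. The hypoxia group passed with DESeq2 (median -0.12) and without shControl replicate 3 (-0.21).

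Neither epithelial nor mesenchymal genes moved as a group. Of 20 epithelial and luminal genes 6 rose and 8 fell, among them the keratin KRT19, which dropped from 437 ± 103 to 141 ± 3.12 CPM (-1.63, SE 0.15, edgeR adjusted p = 5.99e-05), and the tight junction gene CLDN7 (-1.91, SE 0.24, edgeR adjusted p = 2.36e-04). Of 31 mesenchymal genes 6 rose and 12 fell. The collagenase MMP1 went from 615 ± 179 to 64.3 ± 10.3 CPM (-3.26, SE 0.21, edgeR adjusted p = 1.33e-05), while the matricellular gene CCN1 rose from 2005 ± 210 to 4909 ± 36.3 CPM (1.29, SE 0.09, edgeR adjusted p = 1.67e-05). The medians were -0.24 and -0.13 (camera adjusted p = 0.549 and 0.449).

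Mitochondrially encoded RNA made up more of the shRNF20 libraries. Its share of gene counts was 5.74% ± 0.72 against 1.09% ± 0.25 (SD, n = 3), a ratio of 5.25, and all 13 mitochondrially encoded mRNAs tested rose, with a median of 2.65 (camera adjusted p = 1.52e-07, and adjusted p = 0.563 with an estimated correlation). MT-ND1 changed most among them, from 499 ± 44.8 to 5050 ± 657 CPM (SE of the log2 fold change 0.12, edgeR adjusted p = 3.42e-06). Every shRNF20 library lay above every shControl library in this share, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 can give. Of 14 heat shock genes 7 fell and 1 (HSPE1, 0.67) rose, with HSPA1A changed most (-1.42) and a group median of -0.35 (camera adjusted p = 0.0549). The heat shock group passed with DESeq2 (median -0.20), limma-voom (-0.34), no filter on low counts (-0.23) and fry (adjusted p = 0.00627), and without shControl replicate 2 (-0.44) or 3 (-0.43). Ribosomal protein genes went both ways, with 12 of 44 rising and 14 falling, RPS23 changed most (0.93) and a median of -0.01 (camera adjusted p = 0.766) whose sign turned with upper quartile scaling (0.03) and without shControl replicate 3 (0.01).

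Few markers of other cell types were abundant enough to test. Of 18 leukocyte markers 7 were tested: LCP1 (-3.37, the most changed) and CSF1R (-0.80) fell and CD14 (1.12) rose, none of them above 3.99 CPM in a group mean (camera adjusted p = 0.544, median -0.80). Of 15 fibroblast and endothelial markers 5 were tested. COL3A1 (3.18, the most changed), LUM (2.93) and PDGFRB (1.98) rose and PECAM1 (-2.95) fell, with PDGFRB the most abundant of them in shRNF20 at 19.9 CPM (camera adjusted p = 0.488, median 1.98).

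**Figure D3:**
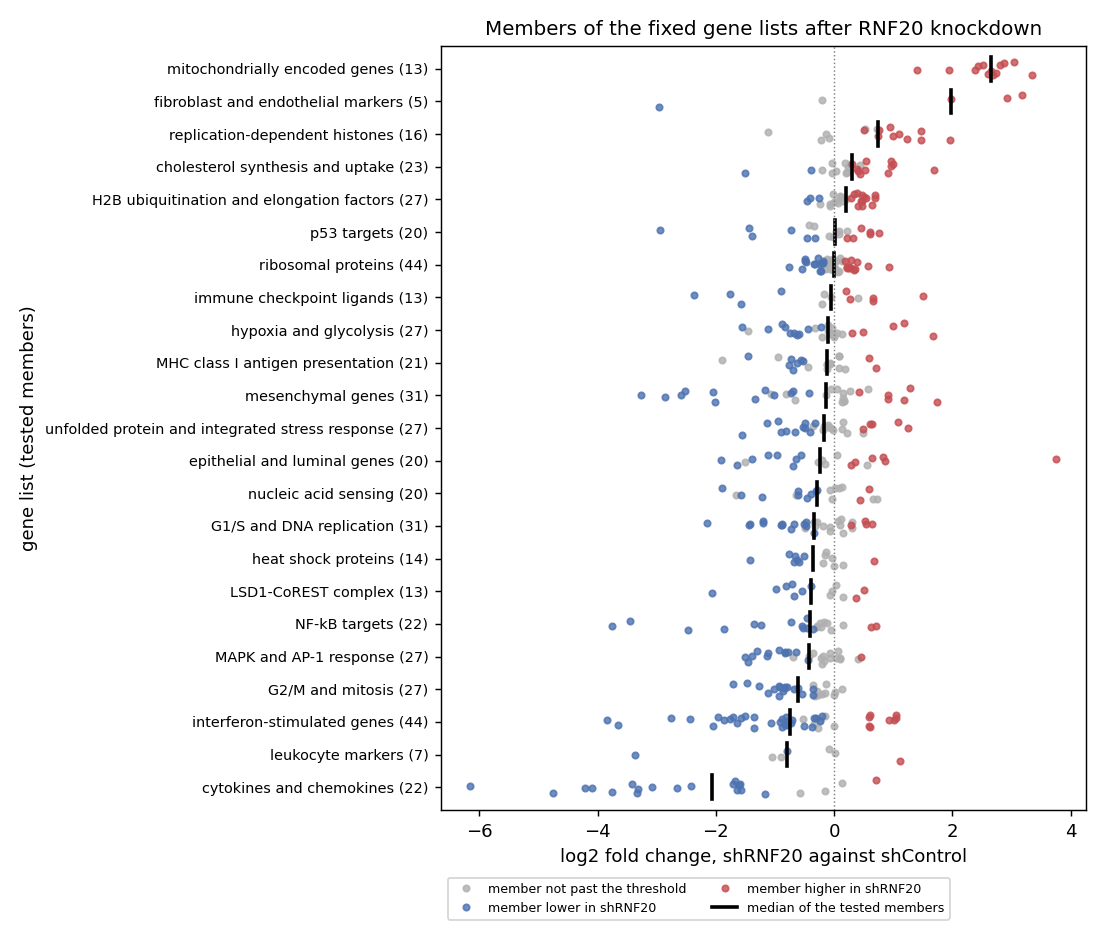
Each point is 1 tested member of a gene list at its log2 fold change, coloured by whether it was higher, lower or not past an adjusted p of 0.05, with the number tested in parentheses; black lines are medians. The cytokines and chemokines have the lowest median (-2.06) and the mitochondrially encoded genes the highest (2.65).

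Of the 23 lists, 9 passed with camera at the preset correlation, 5 of them lower and 4 higher. With an estimated correlation 0 lists passed after adjustment, and 3 had an unadjusted p under 0.05. That form of camera draws its certainty from the few libraries and not from the many genes, so it is stricter even where correlation is low. For NF-kB targets and cholesterol genes the estimates (-0.0029 and -0.0232) were below the preset 0.01, so correlation among members does not account for the loss of those calls. Adjusted over the list alone, member counts differed from those over all genes in 6 lists: 31 lower for interferon-stimulated genes, 3 higher for nucleic acid sensing, 5 lower for checkpoint ligands, 13 lower for NF-kB targets, 7 lower for p53 targets and 1 lower for leukocyte markers. The 3 shRNF20 libraries resembled each other far more than the 3 shControl libraries did (chi-square per gene of 2.04, 5.52 and 6.85 between shRNF20 libraries, and of 30.9, 32.9 and 50.9 between shControl libraries). The labels do not say whether the 3 shRNF20 libraries are separate cultures or repeat libraries of 1 culture, in which case that group would count as 1 sample. Summed to 1 sample, they gave 1753 genes higher and 1619 lower, and 3314 of these 3372 genes were among the 9232 above, all in the same direction.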

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

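The tests of genomic DNA, intronic RNA, poly(A) selection, single control libraries, mitochondrial counts and transcript length were chosen after the results they address were seen; those of gene length and GC content on the immune genes, of slopes within groups and of other splits were chosen before.

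Reads that fell outside annotated exons, introns of genes included, are used by no comparison of genes. They made up 5.33% ± 0.24 of all reads in shRNF20 and 2.49% ± 0.10 in shControl (SD, n = 3). Every shRNF20 library lay above every control (exact permutation p = 0.1, the smallest possible). Mitochondrial RNA was higher in the same libraries. Genomic DNA is argued against: over 405 olfactory receptor genes the shRNF20 libraries held 7.19 more reads than expected from the controls (95% limits -29.0 to 51.5), where DNA at the level of the extra reads would have brought 894. More intronic or nuclear RNA is a possible source of the reads outside exons. The 120 genes annotated inside introns had a median log2 fold change of 0.71 (95% interval 0.58 to 1.19). This interval, like that of the histone genes below, was taken over genes and does not measure the spread between libraries. Intronic or nuclear RNA cannot account for the mitochondrial mRNAs, which are made outside the nucleus and had a median of 2.65. Less strict poly(A) selection also stays open. Of 16 histone genes whose transcripts normally lack tails, 10 rose (median 0.75, 95% interval 0.50 to 1.10, but camera adjusted p = 0.766 with an estimated correlation). Small untailed RNAs of low counts were mostly higher (snoRNA 20 of 21, median 3.39, snRNA 5 of 9, median 2.36, and misc_RNA 5 of 8, median 1.66), which may also reflect intronic RNA. Of single noncoding RNAs examined, NEAT1 (1.24, edgeR adjusted p = 2.00e-04) and MALAT1 (1.80, edgeR adjusted p = 8.99e-04, low counts) rose. RN7SL1 (0.39, edgeR adjusted p = 0.155) and RMRP (-0.28, edgeR adjusted p = 0.520) did not pass. None of these RNAs is mitochondrial, so they do not show that poly(A) selection raised the mitochondrial mRNAs. The 2 mitochondrial rRNAs rose less (median 1.72) than the mitochondrial mRNAs (2.65). The labels name no preparation batch, and an effect of RNF20 loss itself on mitochondrial, intronic or histone RNA stays open and was not tested.

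The fall of cytokine and interferon-stimulated genes (66 tested together, median -0.99) was weighed against 3 technical explanations. After regression on gene span, transcript length and GC content the median was -1.07 (95% interval -1.63 to -0.68). This interval was taken over genes and not over libraries, so it does not measure the spread between samples. Leaving out each shControl library gave medians of -0.92, -1.07 and -1.04, the value closest to 0 being -0.92, and the share of mitochondrial counts could shift other genes by no further than -0.0791 in log2. These values argue against length or GC bias, a single control library and the mitochondrial share of counts as the whole cause. An untested hypothesis is that the knockdown cells express less of these genes, through RNF20 loss or another property of the hairpin cells. A difference in RNA or library preparation between the groups was not tested either. The design, with 1 knockdown group and no batch named, does not separate these.

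The longest genes were lower in shRNF20. Over 12897 protein-coding genes the slope of log2 fold change was -0.0642 per doubling of gene span (SE 0.0042). The SEs of slopes are over genes and do not measure the spread between libraries. In the decile of the longest genes (over 165 kb) the median was -0.41, with 643 of 1290 lower and 167 higher. Deciles 8 and 9 had medians of -0.09 and -0.18. The trend was not steady over all lengths. The shortest decile had a median of -0.01, below those of deciles 2 to 6 (0.07, 0.09, 0.05, 0.04 and 0.02). Transcript length and GC content are argued against, since with both in the regression the slope was -0.0945 (SE 0.0054). Differences between single libraries are argued against too, since the steepest slope of a library against the others of its group was -0.0217. Gene span alone accounts for 1.77% of the variance, and neither a biological explanation nor a difference in RNA or library preparation between the groups was tested.

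Of the 10 splits of the 6 libraries into 3 and 3, 1 (the real one) gave as many genes higher, 1 as many lower and 1 as many lists past the threshold. The real split called 4528 genes higher and 4704 lower, and the highest of the other splits called 0 by edgeR (49 to 114 genes at an unadjusted p under 0.05, against 9983). The real split put 9 lists past the threshold and the highest of the others 7, none of the 9 other splits having fewer than 5. With 10 splits a share under 0.05 cannot be reached. Each other split also mixes shControl and shRNF20 libraries, so the difference between the groups widens its spread and holds down its calls. The low gene counts of the other splits therefore do not measure how many calls chance would give.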

How the results depend on the processing

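The summed shRNF20 sample and the fit without mitochondrial genes were chosen after the data were seen. Over 16 alternatives, 820 of 827 values of the 52 named genes kept direction and call, 7 lost the call and none reversed: ADAMTS9, DSP, CDK9, RNF40, CALR and CST1 with the shRNF20 libraries summed, and CST1 without a filter. RNF20 ranged from -2.33 to -2.15. Over all genes, the sum of the strand columns shared 8722 calls with the main fit, of which 8673 kept their direction and the rest reversed. In the other fits every shared call kept its direction. Genes higher and lower numbered 1753 and 1619 with the libraries summed, where the spread comes from the controls alone, and 1655 and 1856 at 2-fold or more; leaving out 1 library gave 3617 to 4755 higher and 3906 to 5022 lower. Replicate numbers showed no sign of pairing the samples (correlations of -0.02, 0.03 and 0.03), and not every sample correlated best with its own number. Because the shRNF20 libraries differ little from each other, these correlations cannot show that the samples are unpaired. The replicate block gave 8936 calls against 9232, 8722 of them shared. Under the block the H2B list no longer passed (median 0.21) and the ribosomal median turned (0.00032), with no other change. With an estimated correlation the lists of interferon-stimulated genes (-0.75), cytokines (-2.06) and H2B factors (0.21) no longer passed. The H2B list also failed without a filter (0.14), with the libraries summed (0.23) and without mitochondrial genes (0.20), and spanned 0.17 to 0.22 with 1 library left out. LSD1-CoREST passed with DESeq2 (-0.41) and fry (-0.40), MHC class I with DESeq2 (-0.14) and without shControl replicate 3 (range -0.25 to -0.12 with 1 library left out), nucleic acid sensing with fry (-0.30). Checkpoint ligands passed with fry as higher, against a median of -0.0537, and turned with a stricter filter (0.0915) and without shControl replicate 1 (range -0.22 to 0.0528). Groups near 0 or of few members reversed without passing: p53 targets with DESeq2 (-0.0218), no filter (-0.0506) and 1 library left out (-0.0551 to 0.0179); ribosomal proteins with upper quartile scaling (0.0294), limma-voom (0.00079), a stricter filter (0.0111), strand sums (0.0198), summed libraries (0.0183) and 1 library left out (-0.0681 to 0.0143); fibroblast and endothelial markers with DESeq2 (-0.50) and no filter (-0.51), both of which test more members. Other causes were not tested. Of the 23 lists 19 never reversed, and 12 kept direction and call under all settings but the other set tests.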

Other observations

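The tests of gene families and the ranking by position were chosen after the data were seen. Protein-coding genes were grouped by the stem of their symbols, and 93 groups of at least 15 tested genes were compared with all other protein-coding genes by Fisher's exact test with Benjamini-Hochberg adjustment; genes are not independent replicates, so the p-values describe these libraries. Zinc finger genes (ZNF), the largest family, had the smallest p, which their number helps to set: 244 of 444 rose and 38 fell, with a median log2 fold change of 0.46, against 3355 higher and 4147 lower of 12453 other genes (adjusted p = 7.17e-32). On chromosome 19, which holds the large ZNF clusters, 138 of 216 rose and 8 fell (median 0.60), while the 756 other genes of that chromosome had a median of -0.03; the 228 ZNF genes elsewhere had a median of 0.32. After regression on gene span, transcript length and GC content the ZNF median was 0.51.

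Some families of nuclear genes for mitochondrial proteins were more often higher. Of 15 TIMM genes, which belong to the inner membrane translocase, 12 rose and 3 did not pass (median 0.47, adjusted p = 0.00191), and of 48 MRPL genes, which encode the large mitochondrial ribosomal subunit, 26 rose and 8 fell (median 0.32, adjusted p = 0.0043). The 29 MRPS genes of the small subunit did not pass as a family, with 10 higher, 4 lower and 15 not passing (median 0.16, adjusted p = 0.763). RNA-binding motif genes (RBM) rose in 21 of 36 cases and fell in 3 (median 0.43, adjusted p = 0.0043). Of 15 aldehyde dehydrogenase genes 13 fell and 2 did not pass (median -0.62, adjusted p = 0.00139), among them ALDH3B1 (-2.21, SE 0.25) and ALDH1A3 (-1.09, SE 0.16).

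By position, windows of 20 Mb with at least 20 tested protein-coding genes were ranked by median. Only the extremes of this ranking are given, and they were not tested. The highest median was that of chromosome 16 from 80 Mb (0.42, 41 of 76 genes higher and 10 lower). Next came chromosome 16 from 60 Mb (0.37, 68 of 127 higher and 22 lower). Chromosome 12 from 120 Mb followed (0.31, 54 of 97 higher and 17 lower). The lowest median was that of chromosome X from 60 Mb (-0.39, 5 of 47 higher and 23 lower). Above it lay chromosome 2 from 140 Mb (-0.35, 7 of 38 higher and 18 lower). Chromosome 1 from 40 Mb came after that (-0.34, 16 of 145 higher and 68 lower). Some of these shifts were not confined to the windows named. Chromosome X as a whole had a median of -0.25 (52 of 399 higher and 161 lower), and chromosome 16 of 0.19 (251 of 588 higher and 132 lower). Chromosomes 12, 2 and 1 as a whole had medians of -0.02, -0.08 and -0.12.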
